A study of Homo sapiens with 77 samples.

How the data were processed

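Bone marrow of patients with knee osteoarthritis was profiled in 77 libraries by 10x Genomics 3' single-cell RNA sequencing, and the labels put all of them in 1 group. The deposited files hold raw UMI counts per gene and cell barcode, per the file headers written by Cell Ranger 3.1.0 (21 libraries), 6.0.2 (7), 6.1.2 (35) or 7.0.1 (14), aligned by the authors to GRCh38. Of the gene tables, 18 list 33538 genes and 59 list 36601, and the 32732 genes found in both were used.

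Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which left 226737 of 339628. The files hold 442 to 12444 barcodes per library. In 113 of 2926 pairs of libraries more than 1% of the smaller library's barcodes were shared (median over all pairs 0.156%). A barcode shared between such linked libraries, 27 in all, was dropped unless 1 copy had at least 5 times the UMIs of the others. Of all barcodes 11430 were dropped by this rule, and 217474 passed it and the other filters. Doublets were scored against simulated doublets among 30 neighbours, and the highest scores were removed at 0.8% per 1000 barcodes, 10257 barcodes in all (4.72%). No pair of libraries held the same counts: at most 0.172% of barcodes had the same UMI total and at most 2.3% of genes the same sum. That check cannot detect the same cells sequenced or counted again. The 250-gene and shared-barcode filters were chosen after the files had been seen.

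Up to 600 cells per library (44263 in all) were clustered on 2000 variable genes with 40 principal components, 15 neighbours and the Leiden method at resolution 2.0, and the remaining cells took the cluster of their neighbours. The genes of the 16 fixed lists, HLA, heat shock, mitochondrial, ribosomal, immunoglobulin and T cell receptor variable genes and sex-linked genes were left out of the clustering. The genes compared thus did not enter it themselves. Genes related to them, such as CCL3L1 and CCL4L2, were not left out, so the comparisons are not fully independent of how cells were grouped. Clusters were named from 164 fixed markers, with at least 3 raised markers of a class. A cluster stayed unnamed when most of its cells came from 1 library, when its leading genes belonged to another class, or when a pair of classes led equally. These conditions were set after the clusters had been seen. Names describe marker expression and stand for cells like that class.

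Shares were computed over all cells and over cells outside the erythroid, platelet and unnamed classes, with 95% Wilson intervals for shares of single libraries. Ratios within a lineage needed at least 20 cells in the denominator. For comparisons of classes, raw UMI counts were summed per library and class where both classes had at least 10 cells. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, 2-sided) with the library as a block, since both sums come from the same library. Dispersion was estimated within the quasi-likelihood fit, a choice made after timing the fits, and a fit with trended dispersion was added as an alternative. The SE of a log2 fold change is its size divided by the square root of F. Benjamini-Hochberg adjustment ran over all genes in a fit, and again over each list alone. Mean CPM values (counts scaled to the total of a sum) are TMM-normalised in these comparisons, and unnormalised CPM of the class sum for leading classes and programmes.

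The leading class of 140 ligand, receptor and inflammatory genes was sought among 16 classes with sums of at least 10 cells in at least 20 libraries, on log2 CPM with a pseudocount of 1. Programme levels were means of that value over list genes with at least 10 CPM in both classes, in sums of at least 20 cells. Correlations and sign-flip tests used 100000 resamples, and programme correlations were also set against 1000 random lists matched on expression. Batches are the Cell Ranger version, which was added after the files had been seen, the gene table and the series number in the library name.

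The lists, markers, tests and the rule for named genes were fixed before the data were examined. In each class comparison the rule names up to 3 genes per list with the largest absolute log2 fold change among those with an adjusted p under 0.05 by edgeR's quasi-likelihood test, at least 10 CPM in 1 class and the same direction in at least 80% of libraries, 30 genes at most. For leading classes it names the 4 genes per class with the largest difference. Of 320 list genes 317 could be measured; WARS1, listed under an older symbol, CSF2RA and CD99 were not. Gene positions come from GENCODE release 29 on GRCh38.

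The test was tried on simulated data with known changes between the monocyte classes. It recovered 46 of 61 genes changed 1.5-fold, 57 of 57 changed 2-fold and 57 of 57 changed 4-fold, and called 17 of 5284 unchanged genes (0.322%). The leading-class test recovered 18 of 20 genes at 4-fold and called 0 of 40 unchanged ones. The programme test gave a mean r of 0.70 for a true 0.7. It called 3 of 20 unrelated sets and 13 of a further 200, which were added after the first had been seen.

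Alternatives covered scaling, DESeq2 1.42.0, gene filters, the block, cell minimums, thinning to equal counts, each gene table alone, doublets, clustering resolution, correlation method, pseudocounts and centring within batches. Those without linked libraries, without Cell Ranger 7.0.1, with the smaller gene table, with trended dispersion and centred within version were added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3. Marrow without osteoarthritis and differences between patients were not analysed here.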

Results

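Bone marrow from patients with knee osteoarthritis was profiled by droplet-based 3' single-cell RNA sequencing on the 10x Genomics Chromium instrument. The labels place all 77 libraries in 1 group, knee OA, and name the material BMAC, an abbreviation that they do not spell out. The series contains no marrow without osteoarthritis, so differences caused by the disease were not analysed here. The series title names cell-to-cell crosstalk and immune alterations in this marrow. The comparisons therefore ask which cells were present, how cell classes of the same library differed in inflammatory, antigen-presentation, metabolic and signalling genes, which class expressed each ligand or receptor most, and whether gene programmes rose and fell together in different classes of a library. The labels do not say whether the 77 libraries come from 77 patients. Every error and p-value below measures spread between these libraries, which can include technical spread.

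The depth was uneven. Total UMI counts per library ran from 3390457 to 91487223, with a median of 24537907, over 442 to 12444 barcodes. After filtering, libraries held 187 to 9592 barcodes, with a median of 2539. The median cell of a library had 1224 to 15265 UMIs, 395 to 2393 detected genes and 1.29% to 10.4% mitochondrial UMIs. Of 339628 barcodes in all, 98549 had fewer than 250 genes. In the median barcode of that kind 94.65% of UMIs came from haemoglobin genes. The files fall into batches that the group does not explain: their headers name Cell Ranger 3.1.0 for 21 libraries, 6.0.2 for 7, 6.1.2 for 35 and 7.0.1 for 14, and 18 libraries list 33538 genes where the other 59 list 36601.

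Erythroid and lymphoid cells made up most of the cells that passed the filters. After removal of 10257 predicted doublets, 207217 cells formed 64 clusters, of which 58 were named from fixed markers and 6, holding 5.8% of cells, were not. Markers of immature and mature neutrophils were among those fixed, and no cluster took either name. Barcodes with fewer than 250 genes, rich in haemoglobin RNA, are not counted, so erythroid shares depend on that filter. Late erythroid-like cells (HBB, HBA1, ALAS2) made up 27.2% ± 10.6 of the cells of a library (SD, n = 77), early erythroid-like cells (KLF1, GATA1) 5.01% ± 2.65, and megakaryocyte- or platelet-like cells (PPBP, PF4) 0.781% ± 1.23. Among the remaining named cells, CD4 T-like cells were the most frequent at 26.9% ± 11.3, followed by CD8 T-like cells at 18.0% ± 8.16, classical monocyte-like cells (CD14, VCAN) at 14.2% ± 8.82, mature B-like cells (MS4A1, BANK1) at 11.5% ± 5.76 and NK-like cells (KLRF1, SPON2) at 9.19% ± 4.22. B cell progenitors contributed 5.95% ± 4.06, granulocyte-monocyte progenitors (MPO, ELANE) 4.13% ± 3.94, plasma-like cells (MZB1, JCHAIN) 2.48% ± 4.89 and haematopoietic stem or progenitor-like cells (CD34, AVP) 2.14% ± 2.21. Rarer classes were non-classical monocytes (FCGR3A, CDKN1C) at 1.37% ± 1.08, conventional dendritic cells at 1.35% ± 1.16, gamma-delta or mucosal-associated invariant T cells at 1.197% ± 1.33, plasmacytoid dendritic cells at 0.741% ± 0.673, macrophages (C1QA, C1QB) at 0.664% ± 1.12 and stromal cells (LEPR, COL1A1) at 0.144% ± 0.369. Libraries counted with Cell Ranger 7.0.1 formed clusters of their own, and in most of them several classes were nearly absent. Of these, replicate 62 (3350 non-erythroid cells) had 0% gamma-delta or mucosal-associated invariant T cells and 0.0299% stem or progenitor-like cells. Replicate 75, also counted with 7.0.1, had 0.262% and 1.68%. Low values there can reflect naming, which affects these means and SDs.

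Libraries differed widely, and the highest classical monocyte and plasma cell shares came from libraries that share cell barcodes with others. The classical monocyte share ran from 0.503% (95% Wilson interval 0.0888% to 2.79%, 199 cells, replicate 72) to 51.2% (47.0% to 55.4%, 547 cells, replicate 67), both in linked libraries. Among the 50 libraries not linked in this way it ran from 0.905% (0.540% to 1.51%, 1547 cells, replicate 35) to 24.7% (21.4% to 28.3%, 607 cells, replicate 18). The highest plasma cell share was 33.9% of 171 cells, in knee OA replicate 49 (27.2% to 41.3%), which shared 76.5% of its barcodes with replicate 47 and is linked as well. The highest plasma cell share of an unlinked library was 6.01% of 765 cells, in replicate 37 (4.54% to 7.93%), and the mean over the 50 unlinked libraries was 1.19% ± 1.33. In replicate 50, 82.2% of 3349 cells stayed unnamed (80.9% to 83.5%), so its shares rest on few named cells. These intervals cover counting error only. Unnamed parts were also large in replicates 33 (52.8% of all cells), 47 (31.9%), 36 (31.9%) and 72 (31.3%). The largest unnamed cluster, of 7028 cells, was led by T cell genes such as TRAC, CD3D and IL7R. T cell shares can therefore be too low where many cells stayed unnamed.

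**Figure D1:**
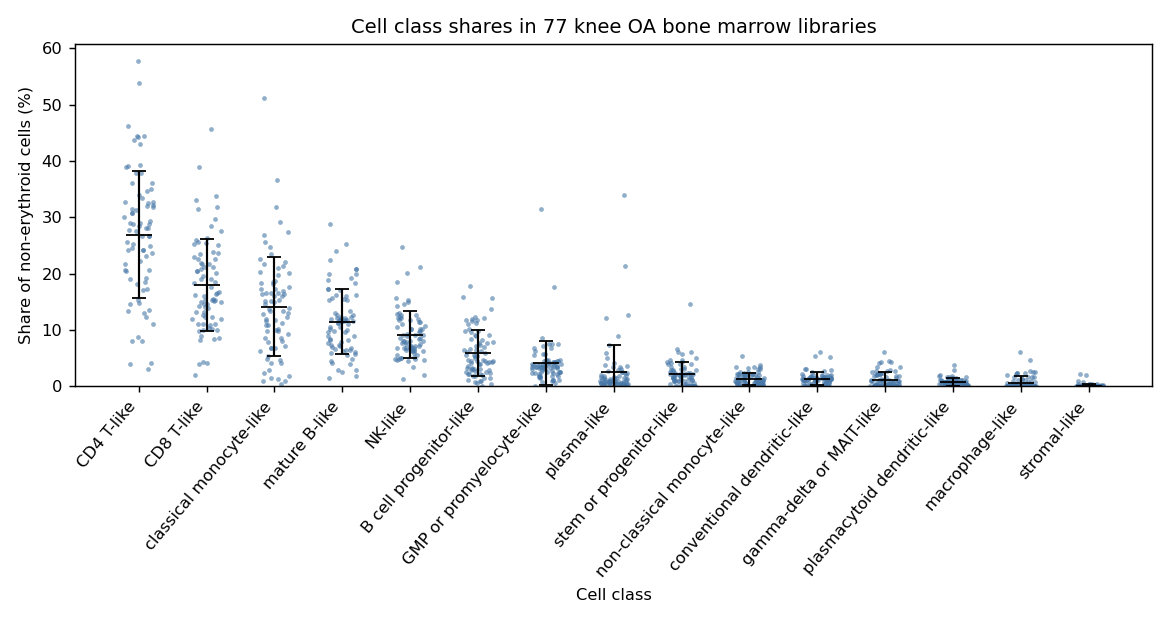
Share of each class among non-erythroid cells, in percent, in 77 knee OA libraries (points), with the mean and SD. CD4 T-like cells had the highest mean, 26.9%, and classical monocyte-like cells ranged from 0.503% to 51.2%.

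The balance within each lineage was set out as 6 ratios. CD8 T cells made up 41.1% ± 15.1 of CD4 and CD8 T cells (SD, n = 75 libraries with at least 20 cells in the denominator). NK cells were 17.7% ± 10.3 of NK and T cells (n = 76), non-classical monocytes 10.9% ± 9.17 of monocytes (n = 72), plasma cells 10.8% ± 14.5 of the B lineage (n = 76), progenitors 33.2% ± 15.9 of the B lineage without plasma cells (n = 73), and late cells 83.2% ± 10.3 of erythroid cells (n = 77). The NK fraction was highest in replicates 36 (63.4%), 50 (54.5%) and 33 (49.8%), where many cells stayed unnamed. Of 13 pairs of ratios that share no cells, 2 correlations passed Benjamini-Hochberg adjustment. A lower late erythroid fraction went with a higher plasma cell fraction (Pearson r = -0.465, permutation p = 0.00278, adjusted 0.0361, n = 76) and with a higher NK fraction (r = -0.398, permutation p = 0.00686, adjusted 0.0446, n = 76), by 2-sided tests with 100000 resamples. Neither held by rank, with Spearman rho of -0.0203 (permutation p = 0.861) and -0.174 (permutation p = 0.133). Without the 2 libraries farthest from the median of the first ratio, r was -0.165 and -0.158, so both relations rest on those samples. Without the 27 libraries linked by shared barcodes, an alternative added after the data were seen, 0 correlations passed, and r was 0.157 for plasma cells and -0.201 for NK cells. They also changed sign between batches. For plasma cells r was 0.290 in the 21 libraries of Cell Ranger 3.1.0, 0.155 in the 7 of 6.0.2, -0.658 in the 35 of 6.1.2 and 0.327 in 13 of 7.0.1, and for NK cells -0.111, 0.451, -0.526 and 0.274. By gene table, r was 0.291 in 18 libraries and -0.504 in 58 for plasma cells, and -0.0368 and -0.389 for NK cells. The other 11 correlations did not pass the adjustment.

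Non-classical monocytes, the FCGR3A-expressing patrolling subset, had far less S100A8, S100A9 and S100A12 RNA than classical monocytes of the same library. S100A12 fell by 7.70 on the log2 scale (SE 0.11, n = 52 libraries), from 1521 ± 655 to 5.53 ± 7.47 TMM-normalised CPM (SD). S100A8 and S100A9, which form the calprotectin dimer released by activated myeloid cells, fell by 5.76 (SE 0.13) and 4.66 (SE 0.09), S100A8 from 17320 ± 6864 to 322 ± 226 CPM. Chemokine receptors parted in opposite directions: CX3CR1, the fractalkine receptor, rose by 1.99 (SE 0.06; 368 ± 119 against 92.5 ± 36.6 CPM), while CCR2, which draws monocytes to inflamed tissue, fell by 7.14 (SE 0.20) and CCR1 fell by 1.95 (SE 0.10). The protease gene CTSL rose by 3.76 (SE 0.10), and THBS1 and VEGFA, encoding thrombospondin-1 and an angiogenic factor, fell by 6.38 (SE 0.19) and 5.71 (SE 0.21). In GRCh38 the 3 S100 genes lie together on chromosome 1, with S100A9 at 153357854 to 153361027, S100A12 (ENSG00000163221) at 153373706 to 153375649 and S100A8 at 153390032 to 153391188, and CX3CR1 (ENSG00000168329) lies on chromosome 3 at 39263494 to 39281735.

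Gene groups divided between the monocyte classes. Of 7 S100 genes 5 were lower and 2 higher, S100A11 (0.59) and S100A4 (0.32), named after their values were seen. Of 18 immediate early genes measured, 16 were lower in non-classical monocytes, 1 was higher and 1 did not pass the test; FOS fell by 2.25, EGR1 by 2.35 and SOCS3 by 3.32. The exceptions, named after their values were seen, were NR4A1, which rose by 0.93, and EGR3 at 0.08. In the TNF and NF-kB list 10 of 16 genes were lower and 4 higher, with lower CXCL8 (-2.55), PTGS2 (-2.13) and IER3 (-3.79). In the list headed inflammasome, NLRP3 (-2.06) and IL1RN (-2.33) were lower as well, among 8 genes of which 4 fell and 3 rose. Interferon genes leaned the other way: 11 of 18 type I genes rose and 5 fell, with LY6E at 1.81 and IFIT3 at 1.49, and 6 of 8 interferon gamma genes rose and 1 fell, with GBP4 at 1.81. Heat shock genes were higher for 9 of 10, HSPB1 by 1.39. MHC class II genes were mixed, 4 higher and 6 lower of 10, with HLA-DMB 2.83-fold lower. Of 15 glycolysis genes 6 rose and 6 fell, among the latter SLC2A3 (-4.54), HK2 (-1.86) and GAPDH (-1.43).

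In this comparison edgeR's quasi-likelihood test, with the library as a block, called 207 of 231 list genes at a Benjamini-Hochberg adjusted p under 0.05 over 5287 genes, 97 higher and 110 lower, and 82 of them changed at least 2-fold. For S100A12, lower in 52 of 52 libraries, the adjusted p by edgeR's quasi-likelihood test was 7.16e-98. Adjusted over the list alone the count was 207. In the 37 libraries of the larger gene table alone it was 202, and 155 in the 15 of the smaller. The falls of CCR2, VEGFA, THBS1 and AREG rest on 5, 8, 23 and 28 UMIs in non-classical monocytes over all libraries, so their size is loosely fixed.

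CD8 T cells, compared with CD4 T cells of the same library, carried cytotoxic-type chemokine RNA. CCL3 and CCL4, which encode inflammatory chemokines, rose by 8.11 (SE 0.09) and 7.30 (SE 0.16; 1735 ± 977 against 15.3 ± 25.9 CPM, n = 74 libraries). XCL1 and XCL2, which attract cross-presenting dendritic cells, rose by 4.47 (SE 0.12) and 6.16 (SE 0.11). CCL3 and CCL4 have near-identical copies, CCL3L1 and CCL4L2, and XCL1 and XCL2 resemble each other closely, so reads can be confused and the level of each gene is uncertain. Those copies were not left out of the clustering, and the CD8 T markers include GZMK, GZMH and CST7. Part of the difference can therefore follow from how the class was formed. CX3CR1 rose by 6.96 (SE 0.11), CXCR6, a receptor for tissue residence, by 2.99 (SE 0.12) and DUSP2, a phosphatase of activated lymphocytes, by 2.86 (SE 0.07). In the other direction IL2RA, the alpha chain of the interleukin 2 receptor found on regulatory T cells, fell by 4.19 (SE 0.13; 1.93 ± 4.46 against 24.0 ± 9.81 CPM), and CCR6, the receptor for CCL20, fell by 3.33 (SE 0.12). CCL3 (ENSG00000277632) lies on chromosome 17 at 36088256 to 36090169 in GRCh38.

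Antigen-presentation genes moved as groups in CD8 T cells. All 9 measured MHC class II genes were at least 2-fold higher, HLA-DQA1 by 3.60, HLA-DRB1 by 2.59 and HLA-DPB1 by 2.15, though HLA alleles and paralogs can share or lose reads. All 12 MHC class I genes rose, with a median of 0.36. TGF-beta signalling genes rose for 6 of 10 and fell for 2, with TGFBR3 at 2.15, the inhibitory SMAD7 at 1.75 and TGFBR1 at 1.15. Immediate early genes were split, 8 higher and 5 lower of 14, with NR4A2 at 1.38 against SOCS3 at -2.13. The TNF and NF-kB list also went both ways, 5 higher and 8 lower of 13, and BIRC3, an NF-kB target, fell by 1.69. Type I interferon genes were lower for 9 of 18 and higher for 3, with MX2 at -0.72 and IFI44L at -1.54 against OASL at 1.83. Heat shock genes fell for 7 of 11, among them BAG3 (-1.64), and oxidative phosphorylation genes for 11 of 20, with a median of all 20 of -0.09. Of 7 matrix turnover genes TIMP1 fell by 1.32 and CTSB by 1.18, and CTSD rose by 0.77.

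Of 209 list genes, 173 passed edgeR's quasi-likelihood test with the library block over 8516 genes, 86 higher and 87 lower, and 53 changed at least 2-fold. Adjusted over the list alone the count was 176. It was 165 in the 56 libraries of the larger gene table and 168 in the 18 of the smaller. For CCL3, higher in 74 of 74 libraries, the adjusted p by edgeR's quasi-likelihood test was 3.64e-112.

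NK cells had far less CD40LG, IL6R, IL7R and CCR7 RNA than T cells. CD40LG, the ligand that helps B cells, fell by 6.86 (SE 0.13) from T cells of all classes to NK cells, and IL6R and CCR7, a lymph node homing receptor, fell by 6.81 (SE 0.14) and 5.56 (SE 0.12). IL7R, which carries the interleukin 7 survival signal, fell by 5.74 (SE 0.11), from 1239 ± 393 to 25.2 ± 24.7 CPM (n = 74 libraries). CXCR2, a receptor for CXCL8, rose by 4.55 (SE 0.14; 30.8 ± 13.6 against 1.32 ± 1.61 CPM). CCL3 rose by 2.13 (SE 0.11) beyond its level in T cells, and the protease genes CTSD and ADAM8 by 1.94 (SE 0.04) and 1.69 (SE 0.05). The IL7R gene (ENSG00000168685) spans 35852695 to 35879603 of chromosome 5 in GRCh38.

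Heat shock, immediate early, NF-kB and energy metabolism genes were mostly lower in NK cells. Heat shock genes fell for 9 of 10, DNAJB1 by 1.55 and HSPD1 by 1.01. The exception, HSPA1A at 0.19, was picked out after its value was seen and has a near-identical copy. In unnormalised CPM, NK, CD4 T and CD8 T cells averaged 136.1, 121.5 and 132.4 for DNAJA1 and 718.7, 539.7 and 678.1 for HSP90AA1. The direction of these genes thus depends on the scaling, while DNAJB1 and HSPD1 were lower in NK cells on that scale too. Immediate early genes fell for 11 of 14 and rose for 2, with SOCS3 at -4.40 and JUNB at -1.43, and TNF and NF-kB genes fell for 8 of 11, with BIRC3 at -3.10 and NFKBIZ at -1.82. Oxidative phosphorylation genes fell for 14 of 20 and rose for 5, with COX7C at -1.09, and glycolysis genes fell for 10 of 13, PKM by -1.09. In contrast 10 of 12 MHC class I genes were higher, by a median of 0.19 over the list. Against T cells pooled, 6 of 7 MHC class II genes were lower, HLA-DRB1 by -1.15. In unnormalised CPM, HLA-DRB1 averaged 53.8 in NK, 25.6 in CD4 T and 159 in CD8 T cells, and HLA-DQB1 15.2, 15.4 and 52.9. For HLA-DRB1 NK cells thus stood above CD4 T cells, so its fall does not hold against every T cell class. TGF-beta signalling genes rose for 6 of 10 and fell for 4, with TGFBR3 at 1.93, SMAD7 at 1.40 and TGFBR1 at 1.32. Interferon gamma genes rose for 7 of 9, although SOCS1, a feedback inhibitor of interferon signalling, fell by 1.12, and type I interferon genes were near balance, 7 higher and 6 lower of 15.

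By edgeR's quasi-likelihood test with the library block, 183 of 198 list genes changed over 7843 genes, 77 up and 106 down, 56 of them at least 2-fold. Adjusted over the list alone the count was 183. It was 171 in the 56 libraries of the larger gene table and 193 in the 18 of the smaller. IL7R was lower in 74 of 74 libraries (edgeR's quasi-likelihood adjusted p = 5.79e-67). CD40LG, IL6R and CCR6 rest on 28, 18 and 36 UMIs in NK cells.

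Plasma cells had little MHC class II RNA. Across all 5020 genes the median log2 difference between plasma and mature B cells was -0.288, so changes are given relative to that median. HLA-DMB, HLA-DRA and CIITA, the master regulator of MHC class II transcription, were lower by -7.14, -6.90 and -6.38 (SE 0.22, 0.23 and 0.23 for the fitted folds, n = 50 libraries). HLA-DRA went from 2987 ± 1067 CPM in mature B cells to 27.5 ± 50.4 in plasma cells. IL4R and LTB were lower by -6.60 (SE 0.23) and -6.01 (SE 0.28), and the follicle and lymph node homing receptors CXCR5, CCR6 and CCR7 by -5.81, -5.17 and -5.11. GAS6, a ligand of TAM receptor kinases, was higher by 7.43 (SE 0.22; 84.1 ± 44.9 against 0.312 ± 0.575 CPM), and the metalloprotease inhibitors TIMP1 and TIMP2 by 5.61 (SE 0.19) and 4.23 (SE 0.16). HLA-DRA (ENSG00000204287) lies on chromosome 6 at 32439842 to 32445046 and GAS6 (ENSG00000183087) on chromosome 13 at 113820549 to 113864067 in GRCh38.

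Of the 12 MHC class II genes 11 were lower in plasma cells, all by at least 2-fold. HLA-DOB alone did not pass, at -0.08 before and 0.21 after subtraction of the median, and was named after its value was seen. MHC class I genes were mixed, with 4 of 11 called higher and 5 lower, none of the latter by 2-fold, and a median of 0.17 relative to all genes. The 4 measured chemokine receptors were all lower. Immediate early genes were higher for 11 of 14, with FOS at 3.52, EGR1 at 3.19 and FOSB at 2.92 after subtraction. All 4 measured S100 genes rose, S100A11 by 2.88 and S100A6 by 1.90. Oxidative phosphorylation genes were called higher for 15 of 20, with COX5A at 2.11. The 3 called lower included COX7C and UQCRB, which stood above the median of all genes, so their direction depends on the scaling. Matrix turnover genes were higher for 5 of 7. In the Toll-like receptor list LY96, the partner of TLR4, was higher by 3.89, while TLR10 and CD180 were lower by -2.87 and -1.41. TGF-beta signalling genes fell for 5 of 6, TGFBR2 by -3.17 and SMAD3 by -2.32. Type I interferon genes were higher for 4 of 11 and lower for 6, with MX2 at -1.98 and XAF1 at -1.74.

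With the library block, edgeR's quasi-likelihood test called 140 of 166 list genes, 68 higher and 72 lower before the median was subtracted, and 74 at least 2-fold. With DESeq2's size factors, which move the median to -0.169, 140 were called, 75 higher and 65 lower, and 133 were the same genes, none with the other sign. Adjusted over the list alone the count was 140. It was 138 in the 39 libraries of the larger gene table and 108 in the 11 of the smaller. HLA-DRA was lower in 50 of 50 libraries (edgeR's quasi-likelihood adjusted p = 3.25e-42). In plasma cells CXCR5, CCR6, HLA-DMB, CIITA, CCR7 and IL4R rest on 4, 15, 20, 21, 25 and 27 UMIs, and GAS6 on 31 in mature B cells, so the size of these changes is loosely fixed.

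**Figure D2:**
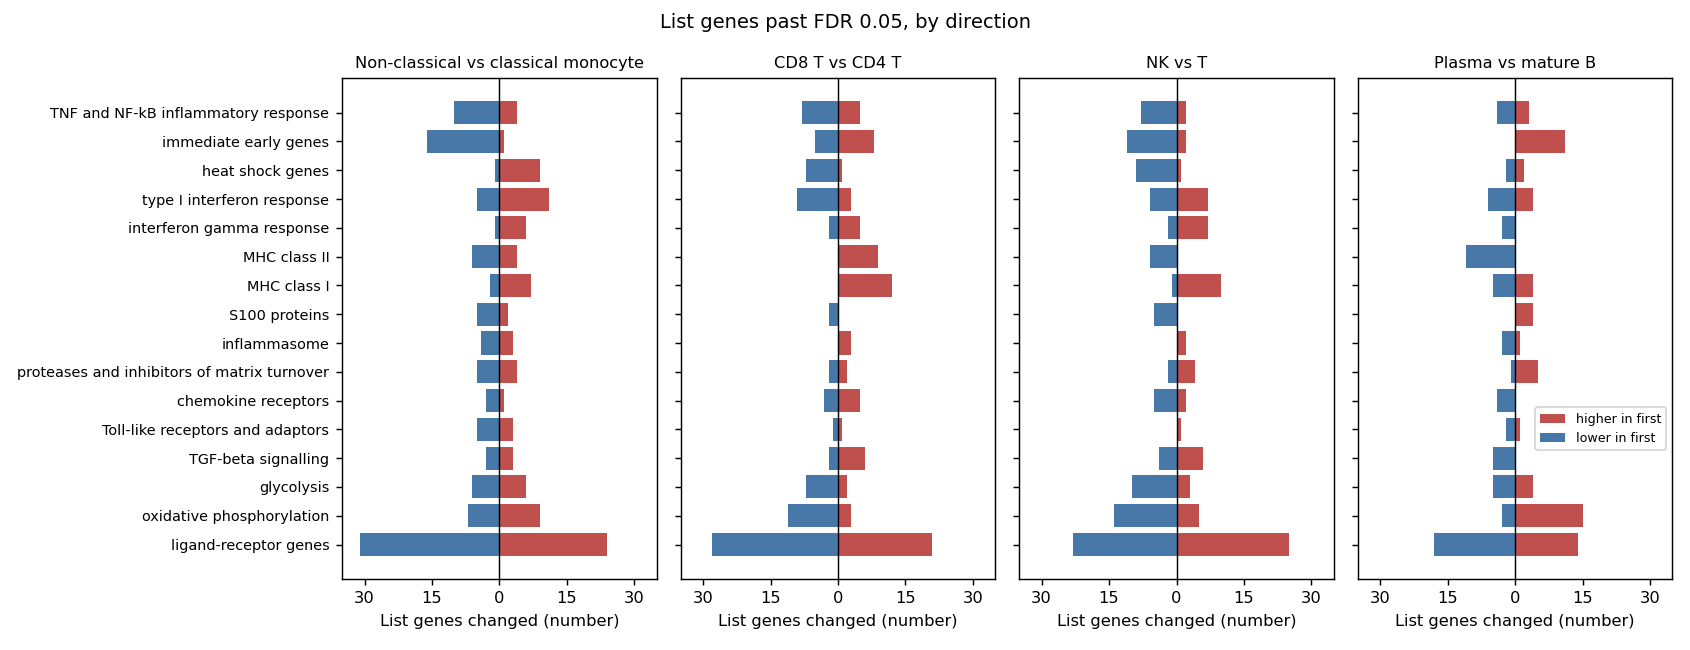
Number of genes of each fixed list that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05, in each of the 4 comparisons of cell classes within a library. MHC class II genes were higher for 9 of 9 in CD8 against CD4 T cells and lower for 11 of 12 in plasma against mature B cells.

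Classical monocytes led more of the ligand, receptor and inflammatory genes tested than any other of the 16 classes compared. Macrophages and stromal cells were not among these classes, nor were neutrophils, since no cluster took that name. The count also depends on which genes the lists hold and on the scale. Levels were unnormalised CPM, so a class dominated by a few transcripts shows lower values for its other genes. On this scale HLA-DOB averaged 43.1 CPM in plasma and 115.7 in mature B cells, although its TMM-scaled difference did not pass the test. Of 140 genes, 107 were higher in their leading class than in the class with the next highest mean, and 29 of these were led by classical monocytes. NK cells, mature B cells and non-classical monocytes led 14 each, plasmacytoid dendritic cells 10, CD4 T cells and gamma-delta or mucosal-associated invariant T cells 7 each, and megakaryocytes or platelets 4. In classical monocytes CXCL8, which recruits neutrophils, reached 221 ± 250 CPM against 23.1 ± 27.7 in granulocyte-monocyte progenitors, and was higher in 69 of 69 libraries. CCR1 reached 164 ± 48.4 and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, 279 ± 157, against 38.0 ± 21.1 and 85.5 ± 72.2 in conventional dendritic cells, both higher in 54 of 54 libraries. Non-classical monocytes led CSF1R (363 ± 92.8 against 70.5 ± 23.7), CXCL16 (146 ± 53.7 against 42.8 ± 20.6) and BCL2A1 (336 ± 101 against 111 ± 54.4), each against classical monocytes and in 52 of 52 libraries.

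Lymphoid and dendritic classes led other parts of the signalling network. NK cells led IL2RB (506 ± 135 against 92.0 ± 29.9 CPM in CD8 T cells, 72 of 72 libraries). They also led CXCR1 and CXCR2 among these classes, which do not include neutrophils. Mature B cells led the BAFF receptor TNFRSF13C (339 ± 93.3 against 40.8 ± 39.7 in B cell progenitors) and CD40 (178 ± 50.9 against 23.5 ± 18.1), each in 66 of 66 libraries, and IL6 (24.7 ± 22.4 against 1.37 ± 2.15 in classical monocytes, 66 of 72). Gamma-delta or mucosal-associated invariant T cells led CXCR6 (93.1 ± 42.3 against 30.2 ± 14.7 in CD8 T cells, 39 of 39) and IL7R (2116 ± 542 against 1317 ± 347 in CD4 T cells, 38 of 39). Plasmacytoid dendritic cells led the nucleic acid sensors TLR9 (113 ± 78.2) and TLR7 (102 ± 44.2), in 35 and 36 of 37 libraries, and APP (792 ± 154). CD4 T cells led IL2RA and CCR7, and plasma cells led TNFRSF13B, a receptor for BAFF and APRIL, in 37 of 50 libraries. Granulocyte-monocyte progenitors led RETN, the gene of resistin (574 ± 327 against 354 ± 353 in classical monocytes, 56 of 69). Late erythroid cells led LGALS3 (472 ± 114 against 326 ± 83.9, 66 of 75), and megakaryocytes or platelets led THBS1 (570 ± 432 against 188 ± 175, 32 of 36).

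These differences were tested by 2-sided sign-flip permutation of log2 CPM with 100000 resamples and Benjamini-Hochberg adjustment over 140 genes; 109 passed unadjusted. For most named genes p was 1e-05, the smallest these permutations can give. The leading class and the next were both chosen from the data, by mean log2 level, so the tests describe these libraries. CCR4 (CD4 T cells, 21 of 35 libraries), ADIPOR2 (early erythroid cells, 46 of 74) and CCL20 (19 of 39) passed with little separation. Megakaryocyte- or platelet-like cells carried HBB at 214400 CPM, and where that RNA came from was not tested.

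**Figure D3:**
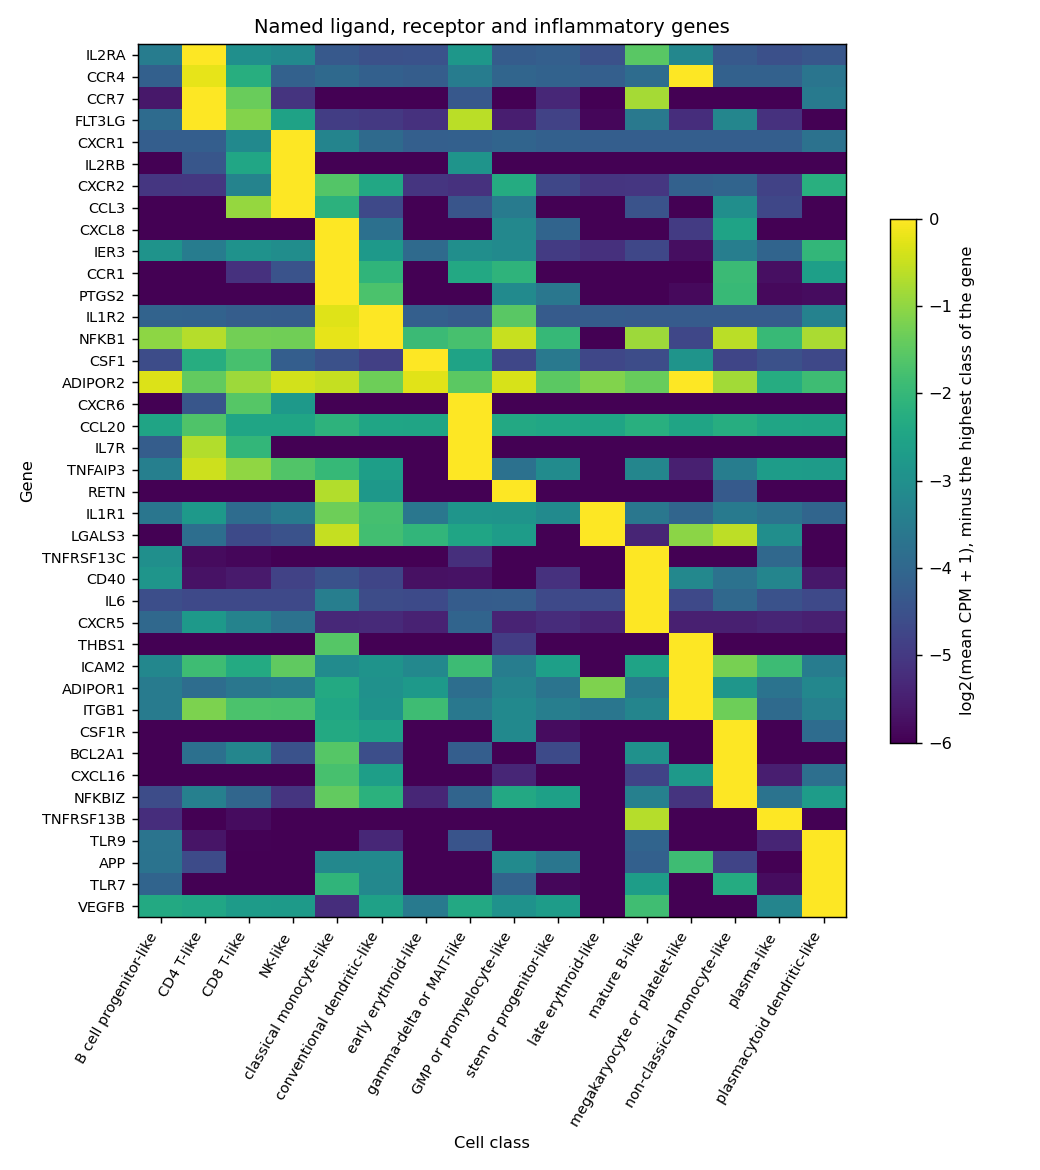
Mean CPM of the named ligand, receptor and inflammatory genes in 16 classes, on the log2 scale with a pseudocount of 1 and relative to the highest class of each gene. IL2RB stood at 506 CPM in NK cells and 92.0 in CD8 T cells; for CCR4 and ADIPOR2, whose leading class was chosen by mean log2 level, megakaryocytes or platelets had the highest mean CPM.

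Programme levels went up and down together in different cell classes of the same library, but random gene lists matched on expression also correlated. Oxidative phosphorylation genes, which encode respiratory chain and ATP synthase subunits, had the highest r over all libraries, a rank lost within some batches: between classical monocytes, T cells, NK cells and mature B cells, taken pair by pair, Pearson r of their mean log2 level ran from 0.832 to 0.934 (n = 66 to 71 libraries). Immediate early genes, such as FOS, JUN and EGR1, had r of 0.587 to 0.888, highest between T and NK cells. Heat shock genes had r of 0.654 to 0.784, MHC class I genes 0.596 to 0.782, type I interferon genes 0.604 to 0.758, TNF and NF-kB genes 0.365 to 0.612 and interferon gamma genes 0.327 to 0.599. Glycolysis genes were the loosest, 0.108 to 0.549, and the pair of classical monocytes and T cells (r = 0.108, permutation p = 0.372) did not pass.

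In this family of 48 correlations all were positive and 47 passed Benjamini-Hochberg adjustment of 2-sided permutation tests with 100000 resamples. The T and NK cell correlation of oxidative phosphorylation had p = 1e-05, the smallest those resamples can give, and an adjusted p of 1.33e-05. Spearman's rho ran from 0.668 to 0.861 for oxidative phosphorylation, with permutation p = 1e-05 in each pair, from 0.592 to 0.863 for immediate early genes and from 0.155 to 0.573 for glycolysis, and 47 passed by rank too. Without the 2 libraries farthest from the median, r for oxidative phosphorylation was 0.784 to 0.938 and for immediate early genes 0.572 to 0.856. Random lists matched on expression also correlated, with median r of 0.579 for lists like oxidative phosphorylation and 0.651 for lists like immediate early genes. It was 0.522 for lists like heat shock, 0.574 like type I interferon and 0.637 like MHC class I genes. For TNF and NF-kB, interferon gamma and glycolysis genes the random medians were 0.519, 0.497 and 0.510. The median r of these programmes was lower, at 0.437, 0.474 and 0.418. Only 7 of the 48 correlations lay above the 95th percentile of 1000 such lists: the 6 of oxidative phosphorylation and that of immediate early genes between T and NK cells. The other 41 did not pass that percentile. The lists were compared over all libraries and not within Cell Ranger versions, so the percentile can include differences between versions.

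Within the batches the median over pairs stayed above 0 for every programme, but its size varied. For oxidative phosphorylation the median r was 0.627 in the libraries of Cell Ranger 3.1.0, 0.773 in 6.0.2, 0.649 in 6.1.2 and 0.895 in 7.0.1, against 0.880 over all libraries. For immediate early genes it was 0.908, 0.369, 0.646 and 0.413, and for heat shock genes 0.429, 0.748, 0.191 and 0.573. By gene table it was 0.661 and 0.886 for oxidative phosphorylation, 0.883 and 0.643 for immediate early genes, and 0.156 and 0.739 for MHC class I genes, the smaller table first. With values centred within the Cell Ranger version, the median r was 0.350 for heat shock genes, 0.488 for MHC class I genes, 0.716 for oxidative phosphorylation and 0.729 for immediate early genes, against 0.740, 0.702, 0.880 and 0.778 before. Centred within the gene table it was 0.725 for heat shock and 0.708 for MHC class I genes. The remaining medians within Cell Ranger versions, in the same order, were 0.166, 0.832, 0.436 and 0.660 for MHC class I genes, 0.722, 0.706, 0.637 and 0.547 for type I interferon genes, 0.262, 0.722, 0.458 and 0.554 for interferon gamma genes, 0.492, 0.421, 0.386 and 0.377 for TNF and NF-kB genes, and 0.432, 0.427, 0.388 and 0.123 for glycolysis. In library-name series 1, 2 and 3 the median r was 0.752, 0.837 and 0.922 for oxidative phosphorylation, 0.7998, 0.671 and 0.258 for immediate early genes, 0.516, 0.429 and 0.832 for heat shock genes, 0.734, 0.376 and 0.806 for type I interferon genes and 0.564, 0.50 and 0.788 for MHC class I genes. It was 0.453, 0.544 and 0.441 for interferon gamma genes, 0.533, 0.451 and 0.243 for TNF and NF-kB genes and 0.259, 0.0956 and 0.277 for glycolysis. Single pairs reversed within some batches. The most negative were classical monocytes and T cells, with r of -0.663 for glycolysis in 7.0.1, -0.564 for immediate early genes in 6.0.2 and -0.243 for TNF and NF-kB genes in series 3, and NK and mature B cells for the last list and series (-0.237).

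**Figure D4:**
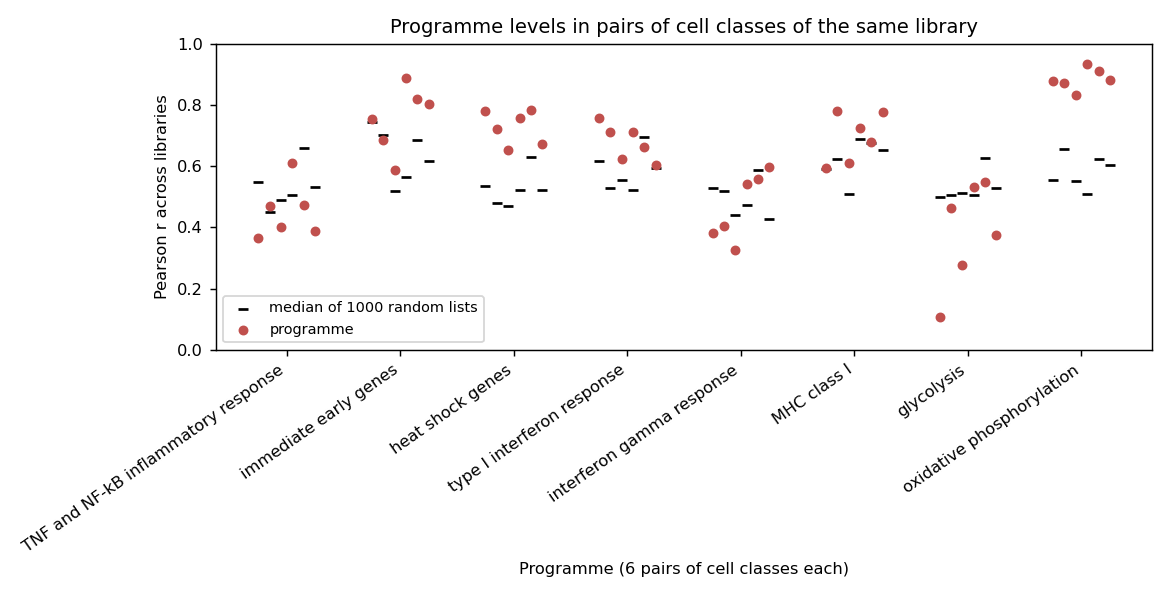
Pearson r across libraries between programme levels in 6 pairs of cell classes (points), with the median r of 1000 random lists matched on expression (bars). Oxidative phosphorylation reached 0.832 to 0.934 against a median of 0.579 for its random lists, and glycolysis 0.108 to 0.549.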

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

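The alternatives without linked libraries, without Cell Ranger 7.0.1, with the smaller gene table, with trended dispersion and centred within version were chosen after the data had been seen. At a clustering resolution of 1.0 no cluster was named plasmacytoid dendritic, so its share was 0 of all cells and 0 of non-erythroid cells, because those cells joined other clusters. The count of ratio correlations was 0 by Spearman, 4 with at least 1000 UMIs per cell and 0 without linked libraries, where the correlation of plasma cells with late erythroid cells reversed to 0.157; the cause was not tested. With no filter on low counts the count of NK minus T genes changed at least 2-fold was 98, and in plasma against mature B cells 228 genes changed, 146 at least 2-fold, since more list genes entered those fits. In the smaller gene table alone every count stayed within 1.5 times.

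Without the library block, 181, 144, 160 and 129 list genes changed in the monocyte, T cell, NK and plasma comparisons, within 1.5 times the main counts. The direction and side of the threshold held for every named gene of the class comparisons under every alternative that measured it, 358, 354, 339 and 351 values for the T cell, NK, monocyte and plasma comparisons. For leading classes 171 values held and 5 lost their call, for ADIPOR2, CCR4 and CCL20. With at least 50 cells per sum, 82 of 140 genes kept their leading class. Of programme correlations 420 values held, 4 gained a call and 4 lost one, and the count stayed between 44 and 48. Depth limits the rarest classes: at least 50 cells per sum left 9 libraries in the monocyte comparison (165 genes changed) and 5 in the plasma comparison (108).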

Other observations

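The tests of intron reads, of Cell Ranger version and of shared barcodes were chosen after the result was seen, and so were the stromal and per-class levels below.

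Libraries counted with Cell Ranger 7.0.1 formed clusters of their own: 17 clusters took at least 80% of their cells from those 14 libraries and held 81.0% of their cells, although these libraries supply 11.1% of all cells. Genes with long introns stood 2.54 log2 units higher, relative to genes with short introns, in their CD4 T cell sums than in the other libraries, with 0.986 as the lowest such library and 0.124 as the highest of the others. After the trend with UMIs per cell was removed 2.505 was left, which argues against depth. Counting of intron reads may therefore be the source, and no biological explanation was tested.

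Oxidative phosphorylation and immediate early gene levels went together across cell classes of a library, with a median r of 0.853 over 12 pairs. The median partial r was 0.8467 on free haemoglobin RNA and 0.8485 on the mitochondrial share, and 0.729 with values centred within the Cell Ranger version. Linear trends with the first 2, or mean differences between versions, thus left most of the median r in place. Centring removes only the mean of each version. The gap between long-intron and short-intron genes ran from 0.986 to 3.016 within 7.0.1, so an effect of intron reads within that version was not tested. Centring lowered the median r of oxidative phosphorylation from 0.880 to 0.716 and that of immediate early genes from 0.778 to 0.729, and random lists were not compared after centring. What lowers r within versions was not separated from other differences between those libraries. Handling of the marrow before sequencing is not in the labels and stays open, as does a difference between patients, and neither was tested.

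In 27 libraries more barcodes were shared with another library than in other pairs, up to 81.8% of the smaller library. A first test on pairs of copies gave a median UMI ratio of 1.33 and was replaced, after it was seen, by the largest copy of each of 3092 barcodes against the next. In 65.3% of barcodes the largest copy had at least 5 times the UMIs of the next, and in 34.7% it had less. For the shared barcodes as a whole, these values argue against a repeated deposit of 1 set of cells. Between replicates 47 and 53, the pair that shared 81.8%, the median UMI ratio was 1.349, and single pairs are not settled. Reads carried from one library into another may explain the sharing, but the first test shows that many smaller copies were of like size. No biological explanation was tested.

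Class labels were swapped within random libraries, in fits with the list genes and 2000 others. For all 4 counts of changed list genes, only 1 of 21 splits, the real one, gave as many. The classes had been separated by expression in the same cells, so the real labels could be foreseen to give more. No conclusion on chance is drawn from this test. The real counts and highest others were 207 and 90 for monocytes, 172 and 75 for T cells, 182 and 101 for NK against T cells, and 138 and 83 for plasma cells.

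Stromal cells were few, 89 in 34 libraries (0.046% of the 195193 cells in named classes), yet held most of the CXCL12 and KITLG RNA counted in those classes. CXCL12 stood at 21820 CPM in the pooled stromal sum. Of its UMIs in the named classes 85.55% came from stromal cells, as did 79.24% of KITLG UMIs. Unnamed cells and predicted doublets were outside these totals. The SPP1 UMIs of stromal cells came from 2 libraries. Of the barcodes in this cluster 36.43% had been removed as predicted doublets, so the number of stromal cells depends on that step. HBB averaged 4144 CPM in CD4 T cells, the lowest class measured, and 408700 in late erythroid cells, and S100A8 23.6 in CD4 T cells against 15740 in classical monocytes. The share of free RNA in a library was not estimated.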
